A study of Homo sapiens with 4 samples.

How the data were processed

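RNA of MCF10-A cells, an established line of non-tumorigenic human mammary epithelial cells, was measured by sequencing of polyadenylated RNA in 4 libraries. Wild-type cells and rho0 cells, the usual name for cells depleted of mitochondrial DNA (mtDNA), had received 20 Gy of ionizing radiation at 0.8 Gy per minute, and the sample names give day 6. The sample descriptions tag the rho0 libraries ddC, which the sources do not explain. Each group held 2 libraries. Per the labels' protocols, RNA was taken with a column kit and libraries were made with a NEBNext Ultra II kit. FastQC, STAR, HTSeq, DESeq2 and genome build hg19 are named in the submitters' processing notes, with no versions. Counting settings, strand use and the gene annotation are not given in the sources used here.

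The authors deposited a table of raw read counts per gene symbol, which also holds 5 rows of reads that were not assigned to a gene. A second table holds log2 values: in each column the authors' value equals log2 of the raw count times 1 factor per library, plus a pseudocount of 1, by comparison of the deposited tables. Another deposited table gives the authors' own comparison of the irradiated groups, with a log2 fold change and p-values per gene. For all 856 genes called here its fold changes were closer to 0 than those fitted to the counts, and its adjusted p-values were computed along with the 5 rows of unassigned reads. The main results here start from the raw counts, and the deposited log2 values enter only 1 alternative.

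The count table numbers its irradiated columns differently from the sample names. The sample descriptions carry the column numbers, and these were followed. The table has 4 further columns of values that match no sample of the series, named as 1 library without the tag for irradiation and 1 more irradiated replicate of each cell population. They were not used, so each group has 2 libraries and there is no unirradiated reference. Reads outside genes were left out of library sizes and tests. Of all reads in the table, those in no annotated feature made up 6.17% and 13.2% in wild-type replicates 1 and 2 and 6.10% and 5.95% in rho0 replicates 1 and 2. Ambiguous reads made up 2.14% to 2.62%, unaligned reads 7.31% to 15.3% and reads aligned to several places 4.79% to 6.08%.

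Counts of 25382 genes summed to between 57961100 and 60753395 per library. At this depth 3 counts, taken as the floor, equal 0.0482 to 0.0544 CPM. Reads are not counted by molecular identifiers, so floors and intervals cover counting error only. The libraries of a group were not repeats of 1 library: the chi-square of their counts per degree of freedom was 740 for the wild-type pair and 136 for the rho0 pair. The series' design text speaks of biological replicas. It does not say whether they came from separate cultures, so p-values measure the spread between these libraries.

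Groups were compared with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr, scaled by TMM factors and tested with the quasi-likelihood F test with group as the only term, which leaves 2 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the 15134 genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are rho0 over wild-type, with standard errors derived from the F statistic. Levels are TMM-scaled CPM, as mean ± SD over the 2 libraries of a group. For a gene with 0 counts in both libraries of a group, a bound was computed against 3 counts per library, in place of the fitted fold.

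A total of 29 gene lists and the rule for named genes were fixed before the data were examined. The named genes are the 10 largest changes in each direction among called genes of at least 5 CPM on average whose groups do not overlap, with mtDNA-encoded genes left out. To these come up to 4 called members of each list with at least 2 CPM, or 2 of the most abundant members where none was called, and a fixed set of interferon, sensing, p53 and stress genes. Of 928 listed entries, 926 were found in the count table and 875 were tested. The table names mtDNA-encoded genes without a prefix, and 13 of 13 matched by gene identifier to the RefSeq table of assembly GRCh38.p14. That table served only for names, gene lengths and the order of genes, and no coordinates are given because the files use hg19. The list of mtDNA-encoded genes had 15 entries, of which the 13 found in the count table, all protein-coding, were tested. The mitochondrial ribosomal RNA genes were not analysed here. Values of some single genes are not reported here. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 at a preset inter-gene correlation of 0.01. Camera was also run with an estimated correlation, where its test has only the 2 residual degrees of freedom of the fit. Fry was run beside it. P-values of lists were adjusted over 28 lists.

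The fit and the list test were tested on simulated data first. In counts drawn for 14857 genes of this comparison, 12% of 50 genes changed by a log2 fold of 1 were recovered, 80% of 50 at 2, 100% of 50 at 3 and 100% of 50 at 4, with 9 false calls among 155. In the simulated lists, the moved list was called and 0 of 28 unmoved lists were. The simulated genes were drawn independently of each other. In the real lists the estimated correlation ran from -0.184 for the endothelial markers to 0.994 for the mtDNA-encoded genes. The simulation therefore cannot show how often camera would call an unmoved list of correlated genes.

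The replicate numbers pair the libraries: the series' design text puts 1 irradiated library of each genotype in each replica. Deviations of same-numbered libraries from their group means correlated at 0.196 across genes. The fit with the replicate number as a block has 1 residual degree of freedom and is given beside a result where it moves a count by over 1.5 times. Other alternatives were RLE and upper-quartile scaling, library size alone, removal of mtDNA-encoded genes, no filter or a filter of at least 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, limma-trend on the authors' log2 values, 2 versions of edgeR's quasi-likelihood fit, an adjusted p under 0.01, a test against a log2 fold of 1, and leaving out each library in turn. With groups of 2, no outlier test within a group applies.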

Results

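Gene expression was compared between wild-type and rho0 MCF10-A cells 6 days after 20 Gy, with 2 libraries per group. The published aim of the study concerns how damage to mtDNA contributes to the innate immune response of irradiated cells, and the comparison asks which transcripts differ when mtDNA is depleted. Both groups were irradiated, so the values describe a difference between the cell populations after irradiation and not a response to it. The rho0 samples carry the tag ddC, the usual short name of dideoxycytidine, a drug that depletes mtDNA, so any effect of that drug goes along with the group. Gene counts were 57961100 and 60753395 in wild-type replicates 1 and 2, and 59396397 and 59947489 in rho0 replicates 1 and 2. Wild-type replicate 2 stood apart from the other 3 libraries. Its 50 most abundant genes took 31.7% of counts, against 18.8% to 19.0% elsewhere, and 13.2% of its reads fell in no annotated feature, against 5.95% to 6.17%. Log2 CPM correlated across genes at 0.956 between the wild-type libraries and at 0.982 between the rho0 libraries, and at 0.912 to 0.957 between groups.

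The transcripts encoded by mtDNA were lower in rho0 cells, which are defined by the depletion of mtDNA, but were still present. All 13 protein-coding genes of mtDNA fell, adjusted over all genes and adjusted over the list alone, with log2 fold changes from -2.62 for ND2 to -4.19 for COX2 and edgeR adjusted p from 0.0179 to 0.0495. COX1 (gene identifier 4512), a catalytic subunit of cytochrome c oxidase, was at 36326 ± 30941 CPM in wild-type and 2017 ± 1309 CPM in rho0 cells (SD, n = 2). These genes took 5.65% and 18.7% of gene counts in wild-type replicates 1 and 2, and 1.54% and 0.588% in rho0 replicates 1 and 2, with Wilson 95% intervals of 5.65% to 5.66% and 1.53% to 1.54% for replicate 1 of each group. The share was 12.2% ± 9.23 in wild-type and 1.06% ± 0.671 in rho0 cells (SD, n = 2), or 10.8-fold lower by geometric means and between 3.68 and 31.8-fold lower for any pair of libraries. An exact permutation test, two-sided, gave p = 0.333, the smallest that 2 against 2 libraries allow. With edgeR, 0 of 13 passed when rho0 replicate 2 was left out or when low-count genes were kept, although 13 had an unadjusted p under 0.05 in either case, and DESeq2 and limma-voom called 13. Camera called the list (median -3.53, or -2.33 without wild-type replicate 2, adjusted p = 1.41e-08, or 0.651 with an estimated correlation). Overlapping frames, such as ATP8 with ATP6 and ND4L with ND4, could share reads. Strand use is not given, so ND6 counts could include reads of the other strand.

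**Figure D1:**
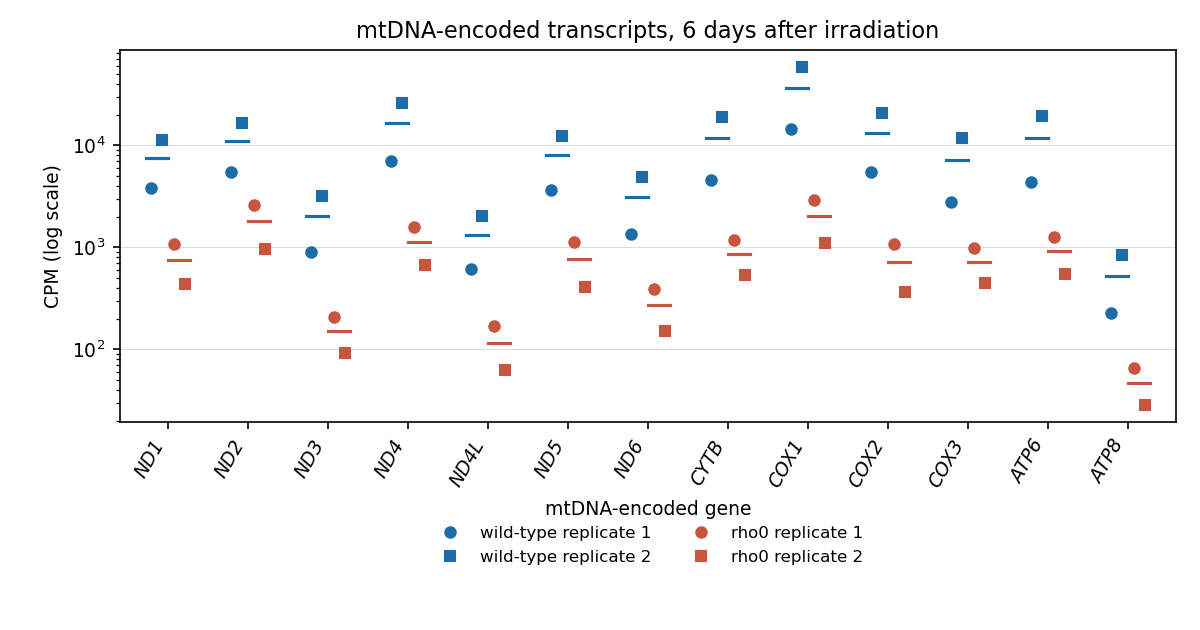
CPM of the 13 mtDNA-encoded protein-coding genes (log axis) in each library, with the group mean as a line over each pair of points. Both rho0 libraries lie below both wild-type libraries for each gene, and wild-type replicate 2 lies above replicate 1.

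Across 15134 genes tested, 372 were higher and 484 lower in rho0 cells, and both libraries of one group lay above both of the other for all 856. Among called genes of at least 5 CPM on average, the largest increases included PHGDH (gene identifier 26227), the first enzyme of serine synthesis, which rose from 2.28 ± 0.0687 to 74.1 ± 41.7 CPM (log2 fold change 5.02 ± 0.49 SE, adjusted p = 0.00209). They also included the scaffold protein AKAP12 (4.36), the glucocorticoid- and FOXO-responsive gene TSC22D3 (4.06), the transcription factors RUNX2 (3.65) and SMAD9 (3.60), CBS of transsulfuration (3.47), the protease CAPN5 (3.42), the pro-apoptotic BMF (3.36), DDIT3 (3.06) and FANCE of the Fanconi anaemia pathway (3.04). At the same minimum of 5 CPM, and with mtDNA-encoded genes left out, the largest decreases were those of OAS2 (-6.09), IFI6 (-5.95), the carboxypeptidase CPA4 (-5.78), S100A8 (-5.69), IFI27 (-5.37), TNNI2 (-5.17), GLYATL2 (-5.13), ISG15 (-4.98), AZGP1 (-4.75) and IVL (-4.32). CPA4 (gene identifier 51200) fell from 344 ± 13.7 to 6.24 ± 3.42 CPM (SD, n = 2, edgeR adjusted p = 0.00135). With the replicate number as a block the count was 2978 (1431 higher, 1547 lower), including all 856, and DESeq2 called 2208. The count rested on single libraries: 5349 without wild-type replicate 1, 2072 without wild-type replicate 2, 493 without rho0 replicate 1 and 167 without rho0 replicate 2. The authors' deposited table lists 874 higher and 1078 lower genes at its adjusted p under 0.05, with 371 of the 372 and 479 of the 484 called in the same direction.

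Interferon-stimulated genes were lower in rho0 cells. Of 68 tested, 37 fell and 0 rose, and adjusted over the list alone 45 fell and 1, GBP2, rose (GBP2 was singled out after its value was seen). IFI6 (gene identifier 2537) fell from 259 ± 6.11 to 4.18 ± 0.623 CPM and OAS2 (gene identifier 4939), which makes the activator of RNase L, from 33.3 ± 8.34 to 0.486 ± 0.245 CPM. ISG15, a ubiquitin-like modifier, fell from 128 ± 81.2 to 4.05 ± 1.30 CPM (log2 fold change -4.98 ± 0.55 SE, edgeR adjusted p = 0.00293). IFI27 (-5.37), OAS1 (-4.21), MX1 (-4.08), IFI44L (-3.89), IFIT1 (-3.15), IFIT3 (-2.72) and IFIT2 (-1.72) fell too. The chemokine CCL5 fell (-3.41, adjusted p = 0.0495), and CXCL10 had 16 and 54 counts in the wild-type libraries and 0 in both rho0 libraries, at least 12.8-fold lower. The list median was -1.73, with or without CXCL10 at its bound, and 65 of 68 members had a negative value. Camera placed the list below other genes (adjusted p = 1.0e-20), but not with an estimated correlation (adjusted p = 0.651, unadjusted p = 0.0257). In fry, the members moved down on balance (adjusted p = 0.0478). Without rho0 replicate 2, 18 members were called, and without wild-type replicate 2, 44.

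Few genes on the list for sensing of foreign nucleic acid passed the main test. Besides sensors and adaptors, this list holds interferons, their receptors and kinases. The sensors DDX58 and IFIH1 and the OAS genes were counted with the interferon-stimulated genes instead. Of 30 tested, 3 fell and 0 rose: IKBKE (-2.54), TMEM173, the gene of STING (-1.50, adjusted p = 0.0311), and IFNL2, singled out after its value was seen, which was at least 11.7-fold lower with 0 counts in rho0. Adjusted over the list alone 5 fell, and with the replicate block 6. The RNA sensor DDX58 (RIG-I), itself induced by interferon, fell by 2.85 on the log2 scale (adjusted p = 0.00476). IFIH1 (MDA5) had -0.73 (adjusted p = 0.167), its adaptor MAVS -0.49 (adjusted p = 0.421) and IFNL1 -4.39 (adjusted p = 0.0663, or 0.00155 with the replicate block). The IFNL1 value rested on 21 and 61 counts in wild-type replicates 1 and 2, and 0 and 4 in rho0 replicates 1 and 2. Its rho0 mean of 0.0329 CPM lay below the floor, so the size of the fold is uncertain. IFNB1 had 0 to 2 counts per library and was not tested, nor was IL6. IFNL2 could share reads with its near-identical neighbour IFNL3. Camera did not call the list (adjusted p = 0.0762), except without wild-type replicate 2 (adjusted p = 0.0145). Of 21 genes of MHC class I presentation, 1 fell, the transactivator NLRC5 (-1.56), against 0 adjusted over the list alone and 3 lower and 1 higher with the replicate block. B2M (-0.28, adjusted p = 0.636) and HLA-B (0.18, adjusted p = 0.772) did not pass, and HLA-B was at -0.09 without wild-type replicate 2. Camera did not call the MHC list (adjusted p = 0.285), though fry gave a downward balance (adjusted p = 0.0478).

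Genes of squamous differentiation were lower in rho0 cells. Of 32 tested, 21 fell and 0 rose, and 27 fell adjusted over the list alone. The calprotectin subunits S100A8 (122 ± 105 to 2.36 ± 0.431 CPM) and S100A9 (119 ± 40.8 to 7.31 ± 0.554 CPM) both fell (log2 fold changes -5.69 and -4.03). The keratin KRT4 fell by 4.92 and IVL, involucrin of the cornified envelope, by 4.32 (41.2 and 18.5 CPM in the wild-type libraries, 2.54 and 0.444 CPM in the rho0 libraries). The median was -2.92 and camera called the list (adjusted p = 3.8e-16), though not with an estimated correlation (adjusted p = 0.651). Of these members, 24 were called without wild-type replicate 2 and 9 without rho0 replicate 2. Among 23 basal epithelial genes 3 fell, the keratins KRT15 (-2.74), KRT5 (-2.14) and KRT6B (-1.35), and 0 rose, against 7 lower and 3 higher adjusted over the list alone and 7 lower and 4 higher with the replicate block. KRT5 went from 4214 ± 371 to 955 ± 299 CPM. Among 10 luminal markers KRT8 (-1.76) and MUC1 (-1.59) fell and XBP1 (2.00), also a factor of the unfolded protein response, rose, with 5 lower and 1 higher both over the list alone and with the block. Camera called neither the basal (adjusted p = 0.285) nor the luminal list (adjusted p = 0.111), though it called the luminal list downward with a filter of 1 CPM (adjusted p = 0.0494). S100A and keratin genes belong to families of similar sequence, so reads could be split between members.

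Genes induced through ATF4, the transcription factor of the integrated stress response, were higher in rho0 cells. Of 45 tested, 25 rose and 0 fell, and adjusted over the list alone 31 rose and 2 fell. Besides PHGDH and CBS, the list held DDIT3, the pro-apoptotic factor CHOP, which rose from 9.03 ± 3.83 to 75.5 ± 54.6 CPM, and DDIT4, an inhibitor of mTORC1, which rose from 114 ± 41.9 to 924 ± 538 CPM (log2 fold change 3.02 ± 0.51 SE, edgeR adjusted p = 0.0153). The secreted GDF15, shared with the p53 list, rose by 2.32. ATF4 itself, largely set by translation, had 1.28 (adjusted p = 0.0756, or 0.0143 with the replicate block). The median was 1.54 and camera called the list (adjusted p = 3.0e-14), though not with an estimated correlation (adjusted p = 0.651). Without rho0 replicate 2, 8 members were called, and without wild-type replicate 2, 29. Among 18 genes of endoplasmic reticulum stress, HERPUD1 (2.21), XBP1 (2.00) and DNAJB9 (1.52) rose and 0 fell, with 7 higher adjusted over the list alone and 8 with the block. Camera called this list (median 0.81, adjusted p = 0.00208, or 0.651 with an estimated correlation). Its count was 12 higher and 1 lower without wild-type replicate 1, 7 higher without wild-type replicate 2 and 0 without rho0 replicate 2. Of 13 heat-shock genes edgeR called 0 and DESeq2 called 3 as lower, with 6 lower at an unadjusted p under 0.05 and 3 lower adjusted over the list alone and with the block. Their median was -0.66, with 9 of 13 negative, and camera did not call the list (adjusted p = 0.0991) except with a filter of 1 CPM (adjusted p = 0.0401). The most abundant members, HSP90AB1 and HSPA8, had 0.51 (adjusted p = 0.415) and 0.73 (adjusted p = 0.472). The HSPA8 value rested on wild-type replicate 2. HSPA8 was at 1472 and 308 CPM in wild-type replicates 1 and 2, and at 1558 and 1386 CPM in rho0 replicates 1 and 2.

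**Figure D2:**
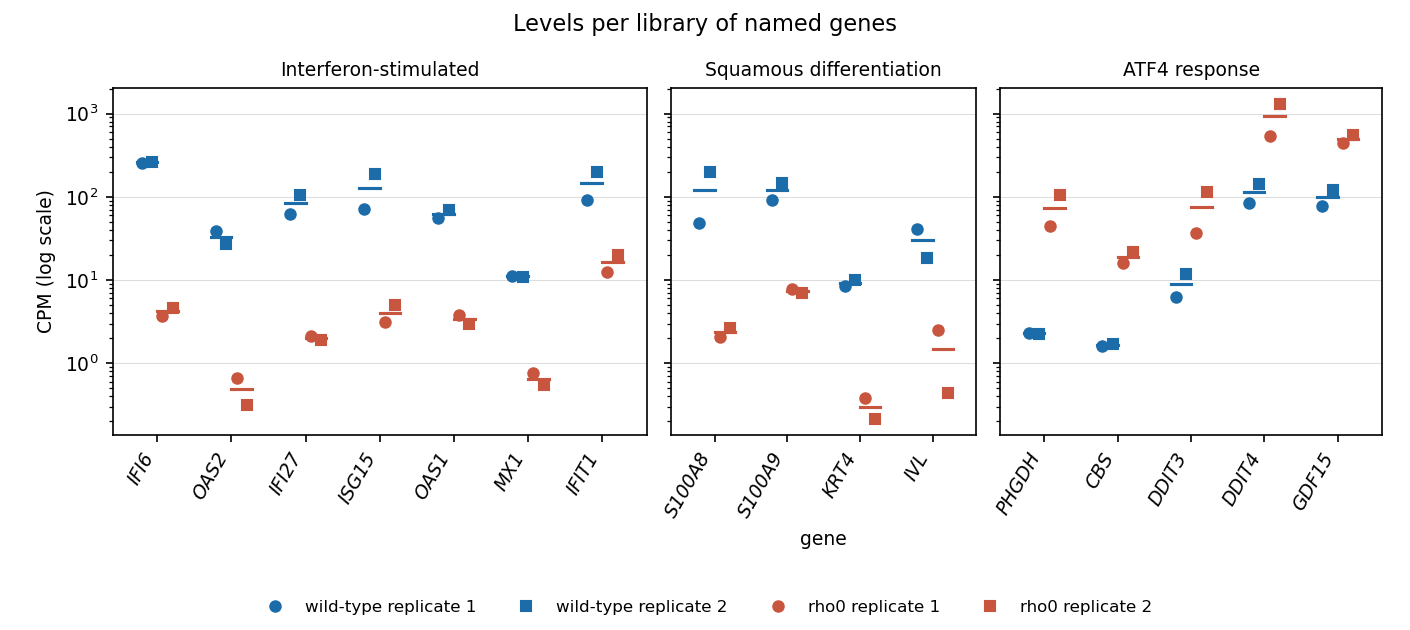
CPM (log axis) of named interferon-stimulated, squamous differentiation and ATF4-response genes in each library, with group means as lines. The rho0 libraries lie below the wild-type libraries in the left and middle panels and above them in the right panel.

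Few nuclear genes of the mitochondrion passed the test. Of 77 nuclear-encoded subunits of oxidative phosphorylation, 1 fell, NDUFC2 of complex I (-2.08, adjusted p = 0.0295), against 0 adjusted over the list alone and 11 with the block. Their median was -0.58 and camera called the list (adjusted p = 0.0091, or 0.838 with an estimated correlation). Wild-type replicate 2 set that value: without it the median was -0.04 (adjusted p = 0.646). The call was also lost without rho0 replicate 1 (adjusted p = 0.397) and when low-count genes were kept (adjusted p = 0.059), but with medians of -0.43 and -0.49. Without wild-type replicate 1 the median was -0.93, and 44 members were lower and 2 higher. Of 76 mitochondrial ribosomal proteins 0 passed in edgeR and 2 were lower in DESeq2, with 4 higher and 12 lower at an unadjusted p under 0.05 (median -0.28, camera adjusted p = 0.361). Adjusted over the list alone 0 passed, and with the block 6 were lower and 2 higher. MRPL3 had 0.28 (adjusted p = 0.616) and MRPS21 -0.99 (adjusted p = 0.204). The MRPS21 value rested on wild-type replicate 2, with 67.6 and 191 CPM in the wild-type libraries and 64.3 and 66.3 CPM in the rho0 libraries. The median was 0.12 without wild-type replicate 2, -0.17 without rho0 replicate 1 and, without wild-type replicate 1, -0.47, with 25 lower and 6 higher members and a camera call (adjusted p = 0.0139). Of 32 genes of mtDNA maintenance and expression 0 passed in edgeR, also adjusted over the list alone, 1 was lower in DESeq2 and 2 with the block (camera adjusted p = 0.608). At an unadjusted p under 0.05, 2 were higher and 4 lower. LRPPRC had 0.72, LONP1 0.38 and TFAM, which packages mtDNA, -0.39 (adjusted p = 0.493). Among 17 mitochondrial chaperones and proteases SPG7 fell (-1.37), against 2 lower over the list alone and with the block (camera adjusted p = 0.961).

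In carbon metabolism, PDK4, which restrains pyruvate dehydrogenase, rose from 107 ± 10.8 to 841 ± 196 CPM (log2 fold change 2.97, edgeR adjusted p = 0.00646), and TXNIP, which limits glucose uptake, rose by 1.79. They were the 2 of 30 glycolysis and lactate genes to change, against 4 higher and 1 lower adjusted over the list alone and 6 higher and 2 lower with the block (camera adjusted p = 0.361). Of 23 enzymes of the citric acid cycle IDH2 rose (2.00), also the 1 call over the list alone, and 2 were higher with the block (camera adjusted p = 0.435). Of 23 cholesterol synthesis genes STARD4 rose (1.75), with 1 higher and 1 lower over the list alone and 3 higher and 2 lower with the block (camera adjusted p = 0.420). Their median was 0.33, but 0.09 without wild-type replicate 1, 0.94 without wild-type replicate 2, -0.49 without rho0 replicate 2 and 0.90 without rho0 replicate 1, where camera called the list upward (adjusted p = 0.00203). Of 30 NRF2 and antioxidant genes AKR1C1 (2.88), FTL (1.99), AKR1C2 (1.89) and TXNRD1 (1.76) rose and GPX3 (-3.24) fell, against 4 higher and 2 lower over the list alone and 7 higher and 2 lower with the block (camera adjusted p = 0.131, but 0.0171 and upward without rho0 replicate 1). The near-identical AKR1C1 and AKR1C2 could share reads. Of 16 hypoxia-response genes LOX (2.52) and P4HA1 (1.74) rose and EGLN3 (-2.82) fell, against 4 higher and 2 lower over the list alone and with the block (camera adjusted p = 0.361). GPX3 and EGLN3 were singled out after their values were seen.

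Mitotic genes were higher in rho0 cells as a list. All 34 tested had a positive log2 fold change, with a median of 1.01, and 3 rose: CDC25C (2.43), BUB1 (2.16) and DLGAP5 (1.92), from 1.15 ± 0.144 to 6.19 ± 3.26 CPM for CDC25C. Adjusted over the list alone 13 rose, and with the block 15. Camera called the list (adjusted p = 3.25e-08, or 0.651 with an estimated correlation). Its count was 19 without wild-type replicate 1, 10 without wild-type replicate 2, 7 without rho0 replicate 1 and 0 without rho0 replicate 2, where the median was 0.54. MKI67 had 0.72 (adjusted p = 0.241). Among 35 S-phase genes CDT1 rose (2.15) and 2 fell, among them UHRF1 (-1.98), against 4 higher and 4 lower over the list alone and 6 higher and 4 lower with the block (camera adjusted p = 0.941). Of 41 p53 targets GDF15 rose and TP53I3 (-2.18) and C12orf5 (TIGAR, -1.96) fell, against 1 higher and 4 lower over the list alone and 3 higher and 6 lower with the block (camera adjusted p = 0.419). The p53 median was -0.31, but 0.08 without wild-type replicate 1. It was -0.29 without wild-type replicate 2, -0.19 without rho0 replicate 1 and -0.13 without rho0 replicate 2. The cell-cycle inhibitor CDKN1A stood at 991 ± 390 and 1043 ± 14.3 CPM (log2 fold change 0.07, adjusted p = 0.927), with a negative value under upper-quartile scaling (-0.03) and without wild-type replicate 2 (-0.28). MDM2 had -0.46 (adjusted p = 0.419). Of 38 NF-kB and secretory-phenotype genes 6 fell, among them the receptor antagonist IL1RN (-3.66), the cytokine LIF (-2.68), the chemokine CXCL1 (-2.34) and LCN2 (-2.13), and 0 rose. Adjusted over the list alone 10 fell and 2 rose, and with the block 13 and 2. CXCL8 had -0.73 (adjusted p = 0.311). Camera called the NF-kB list (median -0.85, adjusted p = 0.00443, or 0.651 with an estimated correlation) but not without wild-type replicate 2 (median -0.38, adjusted p = 0.0722). Its lower members numbered 16 without wild-type replicate 1, 10 without wild-type replicate 2 and 1 without rho0 replicate 2.

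Of 28 mesenchymal-transition genes tested, 22 had a positive log2 fold change. In the test 7 rose and 1 fell, and adjusted over the list alone 10 rose and 2 fell. Fibronectin, FN1, rose from 690 ± 561 to 4334 ± 116 CPM (log2 fold change 2.65 ± 0.60 SE, edgeR adjusted p = 0.0356), the transcription factor TWIST1 by 2.45 and the basement-membrane collagen COL4A2 by 1.91, while tenascin C, TNC, fell by 2.93. The block gave 10 higher and 3 lower. Camera called the list (median 0.76, adjusted p = 0.00109, or 0.651 with an estimated correlation). Its higher members numbered 13 without wild-type replicate 2 (median 1.20), 11 without wild-type replicate 1, 4 without rho0 replicate 1 and 0 without rho0 replicate 2. Of markers of other cell types, the 8 leukocyte genes tested held the lysosomal CD68 (2.15) and LAPTM5 (2.09) as higher and 0 as lower, against 2 and 2 over the list alone and with the block (camera adjusted p = 0.608). The 5 endothelial genes held the VEGF receptor KDR as higher (2.11), with 1 higher and 1 lower over the list alone and 1 higher and 2 lower with the block (camera adjusted p = 0.300). Of 4 fibroblast genes 0 passed in edgeR, also adjusted over the list alone, and 0 in DESeq2, while 1 was lower at an unadjusted p under 0.05 and 1 with the block. DCN had -1.09 (adjusted p = 0.142, or 0.0361 with the block) and FAP -0.06 (adjusted p = 0.942), with a positive value for FAP on library size alone and without wild-type replicate 1 or rho0 replicate 2.

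Lists that bear on RNA content were read alongside. Of 76 cytosolic ribosomal proteins 0 passed in edgeR, adjusted over all genes, adjusted over the list alone or with the block, 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Without wild-type replicate 1, 1 was higher and 2 lower, and without wild-type replicate 2, 2 were higher. Their median was 0.15 and camera called the list (adjusted p = 0.0291, or 0.838 with an estimated correlation). The median was -0.05 without wild-type replicate 1, 0.52 without wild-type replicate 2 (camera adjusted p = 7.45e-08), 0.34 without rho0 replicate 1 and 0.06 without rho0 replicate 2. The call was lost with upper-quartile scaling (adjusted p = 0.066), a filter of 1 CPM (0.132), and without wild-type replicate 1 (0.99) or rho0 replicate 2 (0.259). RPL3 had 0.59 (adjusted p = 0.365) and RPL8 0.41 (adjusted p = 0.552). Of 13 histone genes whose transcripts lack a poly(A) tail, 1 fell, HIST1H4H (-3.59), the 1 call over the list alone too, and 4 with the block, 2 without wild-type replicate 1 and 3 without wild-type replicate 2. Their median was -1.28 and camera called the list (adjusted p = 0.00037, or 0.651 with an estimated correlation), except without rho0 replicate 1 (median -0.84, adjusted p = 0.115). Without wild-type replicate 2 the median was -0.78. In all, camera called 11 of 28 lists at the preset correlation, 5 upward and 6 downward. With an estimated correlation it called 0, and 1 had an unadjusted p under 0.05. Of the lists called by camera, only the interferon-stimulated genes passed in fry (adjusted p = 0.0478). Fry gave an adjusted p of 0.0541 for the mesenchymal-transition, 0.0721 for the squamous, 0.139 for the ATF4 and 0.301 for the mtDNA-encoded genes. The remaining called lists had higher values than the squamous genes, up to 0.644 for the cytosolic ribosomal proteins. The 18 lists that camera did not call or test held 16 higher and 16 lower members. These numbered 81 and 93 without wild-type replicate 1, 41 and 47 without wild-type replicate 2, 15 and 5 without rho0 replicate 1, and 3 and 0 without rho0 replicate 2.

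**Figure D3:**
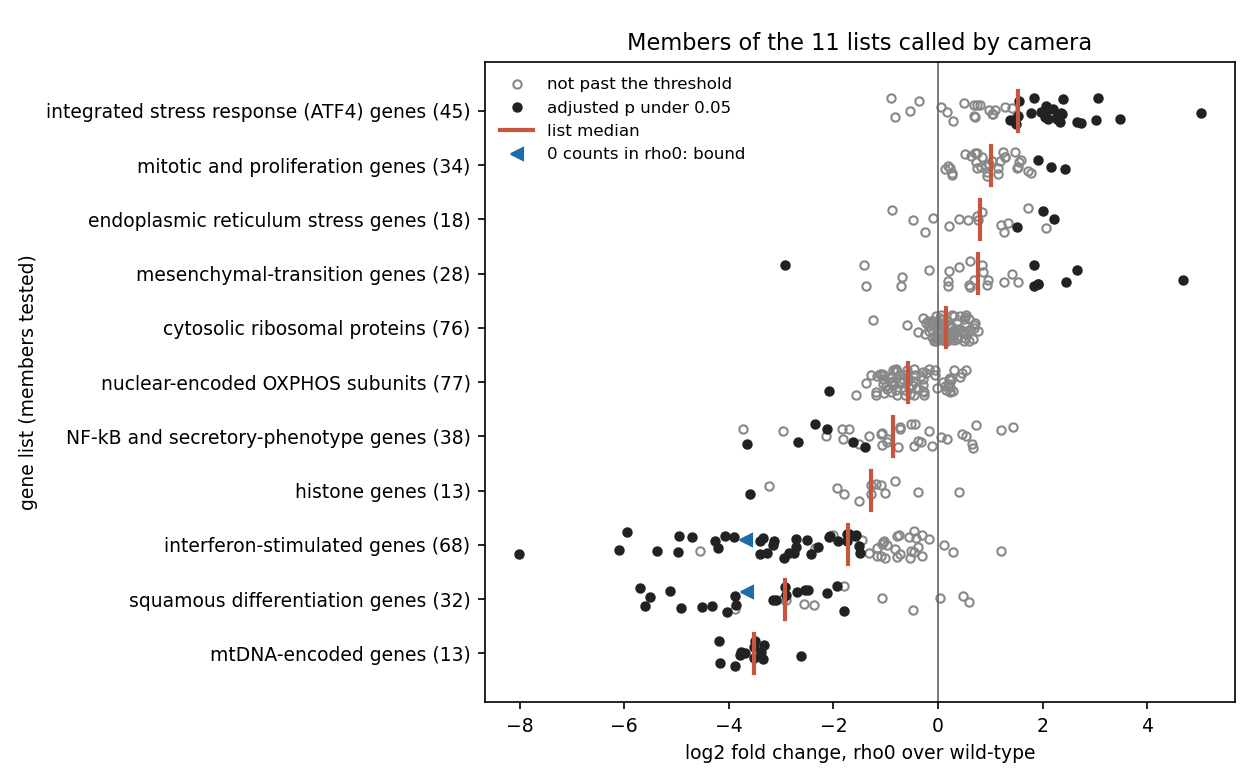
Log2 fold change, rho0 over wild-type, of each tested member of the 11 lists called by camera, with filled points for members at an adjusted p under 0.05, open points for the others and a red line at the list median. Triangles mark genes with 0 counts in both rho0 libraries, drawn at their bound, and the medians run from -3.53 for the mtDNA-encoded genes to 1.54 for the ATF4 genes.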

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

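The squamous and ATF4 counts under all settings, the list counts without wild-type replicate 2 and the bias-adjusted version of edgeR's quasi-likelihood fit were added after the data were seen. With 2 libraries per group, few genes with a log2 fold near 1 could be recovered (12% in simulation), so a gene that did not pass is not shown to be stable. The replicate block raised the count of changed genes from 856 to 2978 and ended no call of the unblocked fit or of camera. DESeq2 gave 2208. Keeping low-count genes gave 165 changed genes, with 0 mtDNA-encoded, 20 interferon-stimulated, 10 squamous and 12 ATF4 genes called. An adjusted p under 0.01 left 77 genes and a test against a log2 fold of 1 left 106. Leaving out single libraries gave 167 to 5349 changed genes, 0 to 13 lower mtDNA-encoded, 18 to 44 lower interferon-stimulated, 9 to 24 lower squamous and 8 to 34 higher ATF4 genes. Without wild-type replicate 1, 1 interferon-stimulated gene was also called as higher and 2 ATF4 genes as lower, and 134 of the 856 calls were kept in all 4 of these fits. With 1 library left in a group, that library is assumed to vary like the other group's pair. The low values came without a rho0 library, when the spread rested on the wild-type pair. The replicate difference of that pair had an SD of 0.911 against 0.621 on the log2 scale for the rho0 pair. Whether this lowered the counts was not tested. The fits also differed by the rho0 library that remained: the mtDNA-encoded median was -4.35 without rho0 replicate 1 and -2.97 without rho0 replicate 2. With an estimated correlation camera called 0 lists in place of 11, and its adjusted p for the interferon-stimulated genes was 0.651 against 4.73e-23 to 1.58e-10 in the other alternatives. With an estimated correlation, camera's test has only the 2 residual degrees of freedom of the fit, so few lists could pass. For the mesenchymal-transition genes the estimate was -0.033, below the preset 0.01, yet camera's unadjusted p went from 0.00027 to 0.0546. The lost calls thus cannot be laid to correlation between genes alone. The causes of the shifts between settings were not tested. No called gene changed sign in any setting. Upper-quartile scaling moved the median log2 fold change of all tested genes from -0.04 to -0.17. FAP turned positive with library size alone (0.015) and ran from -0.52 to 0.34 over the fits without 1 library, CDKN1A turned negative with upper-quartile scaling (-0.026) and ran from -0.28 to 0.61, and HLA-B ran from -0.091 to 0.59. None of these genes had passed the test. Over the 111 named genes and 16 alternatives, 1562 values kept direction and side of the threshold, 179 lost and 14 gained the call, and 41 genes kept both in every alternative. The legacy quasi-likelihood setting, 1 of the 16 alternatives, was the default and gave the same fit, so its values were kept by construction. Genes not called in the main fit counted as kept where they stayed uncalled.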

Other observations

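The FOXO, glucocorticoid and clock gene lists below were drawn up after the genes with the largest changes were known, and the tests of carry-over and of nuclear mtDNA copies were chosen after the mtDNA-encoded levels were seen. The comparison of neighbouring genes with other splits of the libraries was chosen after the values of the blocks were seen. Some genes of the circadian clock rose in rho0 cells. Of 17 tested, 6 rose, 0 fell and 11 did not pass, a count that cannot test the list because the list was chosen for its called members. Those called were the repressor NR1D1 (2.58), the bZIP factors TEF (2.65) and NFIL3 (2.09), the nuclear receptor RORA (2.20), PER1 (1.66) and CRY2 (1.58). The core activators CLOCK (-0.27) and ARNTL (0.56) did not pass, nor did PER2 (-0.05). The Krüppel-like factor KLF9 rose by 2.95, the ubiquitin ligase FBXO32 by 2.18, the cell-cycle inhibitor CDKN1B by 1.85 and the monoamine oxidase MAOA by 2.22, while RGS2, a regulator of G-protein signalling, fell by 2.88.

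TSC22D3, PDK4 and BMF, among the genes that rose most, are known targets of FOXO transcription factors, and the first 2 also respond to glucocorticoids. As a hypothesis, FOXO activity may be higher in the irradiated rho0 cells: of 34 other FOXO targets, 6 rose and 0 fell, 30 had a positive value, and camera gave p = 2.6e-06 (p = 0.306 with an estimated correlation, p = 0.00125 without wild-type replicate 2). The glucocorticoid receptor is a second candidate: of 26 other glucocorticoid-induced genes, 7 rose and 1 fell, with camera p = 0.00223 (p = 0.0986 with an estimated correlation, p = 0.00462 without wild-type replicate 2). Of these 26, 20 had a positive value. FKBP5, a classical target of the receptor, had 0.19 and SGK1 -1.67, and neither passed. CRISPLD2 (-2.74), PTGDS (-2.61) and ANGPTL4 (-1.87) were negative too and did not pass. At the preset correlation both tests came out as the explanations required, so they do not separate them. With an estimated correlation neither p was under 0.05. The lists were drawn up after the top genes were seen, so the tests lend neither explanation independent support. Among the fits without 1 library, only that without wild-type replicate 2 was run for these lists. The FOXO list also holds FOXO1, FOXO3 and FOXO4 themselves. It shares TNFSF10 with the interferon-stimulated list and KLF15 with the glucocorticoid list. In addition, transcript levels of target genes cannot tell activity from a shared metabolic state.

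The rho0 libraries still held 1.54% and 0.588% of gene counts from mtDNA. The levels per base of the 13 genes correlated at 0.905 across genes between rho0 and wild-type cells, against 0.983 and 0.986 between replicates. The profile of reads from nuclear copies of mtDNA was not measured, so these stay open. Of 6262 abundant wild-type genes, 7 in rho0 replicate 1 and 2 in rho0 replicate 2 lay below 0.5 times the level that carry-over of wild-type cells, RNA or reads would bring, fewer than the 10 set for excluding it. It would need 26.9% and 7.11% of wild-type replicates 1 and 2 in rho0 replicate 1, where CPA4 was at 2.59% and 2.45% and OAS2 at 1.68% and 2.41%, and 10.6% and 2.81% in rho0 replicate 2, where CPA4 was at 1.14% and 1.08% and OAS2 at 0.799% and 1.14%. CPA4 and OAS2 thus lay below the needed level against both wild-type libraries, in each rho0 library. For these 2 genes, picked by the search, the values argue against carry-over as the only source at the wild-type shares measured. Carry-over as part of the source stays open, as does incomplete depletion of mtDNA, a biological explanation that was not tested.

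Wild-type replicate 2 had 3.31 times the mtDNA-encoded share of replicate 1 and 19.7 reads outside features per 100 gene counts, against 7.67 to 8.36 elsewhere. Genomic DNA or unspliced RNA could raise such reads. Olfactory receptor genes, silent in epithelium, summed to 2.81 CPM in this library, 1.46 times the highest of the others, less than the 2 times set in advance, while the others differed among themselves by more (0.889 to 1.93 CPM). Less complete selection of polyadenylated RNA could also contribute, but histone genes without a poly(A) tail had a median log2 difference of 0.546 from replicate 1, with 8 of 13 higher, which decides neither way. Both stay open, and a difference in cell state between the replicates was not tested.

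Log2 fold changes of neighbouring genes were alike: the median log2 fold change over 290 blocks of 50 neighbouring genes had an SD of 0.214, and 0 of 1000 random gene orders reached it (highest 0.167). A copy-number difference between the populations could do this. From mean log2 CPM the SD was 0.211 for rho0 against wild-type cells, 0.168 for replicates 2 against replicates 1 and 0.0989 for the remaining split into pairs, and 0 of 1000 random orders reached any of these. Splits that cancel a difference between the groups thus gave such blocks too, so a copy-number difference cannot be told apart from other causes such as clusters of genes regulated together, which were not tested. Of the 290 blocks, 19 had a median beyond 0.4 in either direction, a sign set in advance for a copy-number difference. Such blocks were not counted for the other splits. The lowest block median was -0.66, in a block that ends at SPRR2D, within the cluster of squamous differentiation genes. The highest was 0.452, in the block from UTP14C to FARP1.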
